A study of Homo sapiens with 3 samples.

How the data were processed

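Total RNA of CaSki cells was sequenced in 3 groups of 1 library each: empty vector with GFP siRNA, NANOG with GFP siRNA and NANOG with HDAC1 siRNA. Groups were taken from the overexpression and siRNA labels of each sample. Per the labels' protocols, RNA was taken up in Trizol and libraries were made from 2 ug of total RNA with a TruSeq stranded total RNA kit. Per the submitters' processing notes, TopHat2, Cufflinks and the hg19 build were used; their versions, the gene annotation, the read length and the way strand was handled are not given in the sources used here. The authors deposited FPKM values, 1 per gene symbol and library, scaled to transcript length and to the number of mapped fragments. FPKM already divides by library size and transcript length, so that a few very abundant RNAs in a library lower all of its other values, and a wrong fragment assignment in Cufflinks passes straight into the value. No column of per-sample values was left unused.

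The values summed to 660990 FPKM in the empty vector library, 681947 in the NANOG GFP siRNA library and 600749 in the NANOG HDAC1 siRNA library. Small RNA symbols (1621 of 23277) held 21.2%, 23.1% and 16.0% of these sums and were left out, since FPKM of genes shorter than a fragment is unstable. No symbol was repeated. Symbols listed at 0 numbered 7101, 6748 and 6980. Relative depth was read from 2158 genes under 0.3 FPKM: the share of ratios within 1% of a ratio of whole numbers up to 6 was 59.0% for empty vector with NANOG, 60.7% for HDAC1 siRNA with NANOG and 61.7% for empty vector with HDAC1 siRNA, where evenly spread ratios would give 12.4%. The most frequent ratios were 1.018, 1.002 and 1.017. The number of fragments behind a value stayed unknown, so no interval was given.

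Differences were taken as log2(FPKM + 1) with a pseudocount of 1 FPKM, among 11401 genes with a mean of at least 1 FPKM over the 3 libraries. Genes with a difference of at least 1 in size, or 2-fold on this scale, were counted. There was no test, because each group had 1 library. A gene was counted as listed at 0 when it was at exactly 0 in a library and at 5 FPKM or more in another; no fold is given for it.

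The rule for named genes was written before the data were examined. It took, per comparison, the 12 genes with the largest positive and the 12 with the largest negative difference among genes with at least 5 FPKM in the higher library, without symbols of small RNAs or starting with LOC. It added 10 genes per direction of opposite change, NANOG, HDAC1 and 5 genes of the study, and up to 4 members of each described list with the largest change. Some genes that the rule takes are not reported here. Names outside it are said to have been chosen after their values were seen. A set of 28 gene lists was also fixed before the data were examined, and 25 had at least 3 measured members. Each list's median difference was placed among 10000 random lists of the same size drawn from the same 10 classes of mean expression. A list stood apart under percentile 2.5 or above 97.5, as a description of these libraries. To give the chance level of opposite changes, each gene's values were reassigned at random among the 3 libraries 1000 times, and the overlap of independent lists was computed from the counts.

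The steps were tested on simulated data made from the NANOG and empty vector libraries. With noise of 0.15 on the log2 scale, 100 of 100 genes changed 3-fold and 100 of 100 changed 4-fold were recovered, and 0 of 11228 unchanged genes passed. The changed genes had a mean of at least 5 FPKM, and the same noise was set at every expression level. Noise between replicates of these cells is unknown, so this checked the steps and gives no rate of false calls. Of 100 lists of 20 genes drawn at random, 4% of unshifted lists fell outside the limits and 93% of lists shifted by 0.3 lay above. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Transcript length, GC content and the densest 30-codon window of codons starting with GA in the longest open reading frame came from GENCODE release 29 transcripts and covered 10805 genes (94.8%). This reference is not the hg19 build of the values, so no coordinates are given.

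Alternatives chosen before the data were examined were pseudocounts of 0.1 and 0.5 FPKM, no filter and a filter at 5 FPKM, rescaling to the same upper quartile, to a median log2 ratio of 0 or to TPM, small RNAs kept, the largest entry of a repeated symbol, thresholds of 1.5-fold and 3-fold, and the mean of a list in place of its median. The sums used for TPM included the small RNA symbols. Added after seeing the data were leaving out genes listed at 0, removing the median of 20 bins of transcript length, and leaving out genes with a share of 0.6 or more codons starting with GA in the densest window. Empty vector cells with HDAC1 siRNA were not analysed here, so the effect of HDAC1 siRNA without NANOG has no value.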

Results

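RNA sequencing of CaSki cells, an established line from an epidermoid cervical carcinoma that carries human papillomavirus, was used to look for genes regulated by NANOG together with HDAC1. NANOG is a homeobox transcription factor of pluripotent cells, and HDAC1 is a histone deacetylase of several corepressor complexes. The 3 libraries came from empty vector cells given an siRNA against GFP as control, from cells carrying FLAG-tagged NANOG in a retroviral vector and given the GFP siRNA, and from NANOG cells given an siRNA against HDAC1. Each group held 1 library, so no difference below has a replicate check, and no p-value, standard error or interval could be given. Each library had FPKM values (fragments scaled to transcript length and to the number of mapped fragments) for 23277 gene symbols, of which 11415 were at 1 FPKM or more in the empty vector library, 11466 in the NANOG GFP siRNA library and 11442 in the NANOG HDAC1 siRNA library. Absolute depth was unknown, since the values are not read counts. Ratios of low values, which move in steps of single fragments, put the depth of the empty vector library within 1.018-fold and that of the HDAC1 siRNA library within 1.002-fold of that of the NANOG GFP siRNA library. Across the 11401 genes kept for comparison, Pearson's r between libraries was 0.975 for empty vector with NANOG, 0.984 for empty vector with HDAC1 siRNA and 0.989 for the 2 NANOG libraries; genes are not independent replicates.

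NANOG followed the labels, and HDAC1 was lowest in the HDAC1 siRNA library. NANOG stood at 0.0357 FPKM in empty vector cells, at 298 FPKM in NANOG cells with GFP siRNA and at 325 FPKM in NANOG cells with HDAC1 siRNA. HDAC1 stood at 19.02 FPKM in empty vector cells, at 108 FPKM with NANOG and at 12.8 FPKM with NANOG and HDAC1 siRNA. The HDAC1 difference was thus 2.45 on the log2(FPKM + 1) scale for NANOG against empty vector and -2.98 for HDAC1 siRNA against GFP siRNA. Against empty vector cells, HDAC1 in the HDAC1 siRNA library differed by only -0.54. Most of the -2.98 therefore rests on the high value of the NANOG GFP siRNA library, for which the labels give no reason. The related deacetylase HDAC2 was at 17.7, 17.0 and 17.8 FPKM in the same order and HDAC3 at 48.3, 42.2 and 39.2 FPKM, both named after their values were seen. Of the genes recalled from the study itself, CDKN2D, which encodes the CDK inhibitor p19, was at 5.99 FPKM in empty vector cells, 3.97 FPKM with NANOG and 4.19 FPKM with HDAC1 siRNA. CDKN1B, which encodes the CDK inhibitor p27, was at 30.7, 23.7 and 28.3 FPKM. TRIM17, an E3 ubiquitin ligase, was at 3.43, 2.34 and 2.77 FPKM, and PMAIP1, which encodes the BH3-only protein NOXA, at 55.2, 52.9 and 62.5 FPKM. The survival gene MCL1 was at 54.1, 46.7 and 61.0 FPKM.

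**Figure D1:**
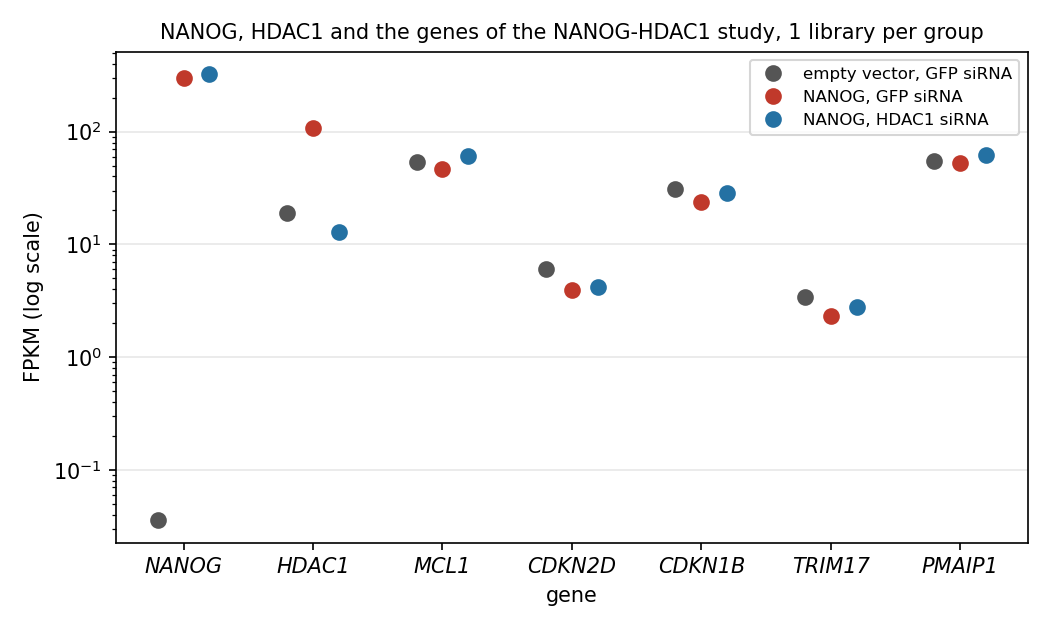
FPKM on a log axis of NANOG, HDAC1, MCL1 and the 4 genes of the study, 1 point per library. NANOG lies at 0.0357 FPKM in empty vector cells and at 298 and 325 FPKM in the NANOG libraries, and HDAC1 peaks at 108 FPKM in the NANOG GFP siRNA library.

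The first comparison asked which genes differed between NANOG and empty vector cells, both with GFP siRNA. Genes of hypoxia and glycolysis were lower with NANOG, and so were most genes of cholesterol synthesis and epithelial identity. Most members of the joint list of unfolded protein and amino acid stress were lower too, while interferon-stimulated genes were higher as a group. Carbonic anhydrase CA9 differed most among the hypoxia genes, at 11.3 FPKM in empty vector and 0.389 FPKM in NANOG cells. Of the 11401 genes, 77 were at least 2-fold higher and 139 at least 2-fold lower on the log2(FPKM + 1) scale, which understates the change of low genes. Of these, 2 higher and 6 lower genes were listed at exactly 0 in 1 library or more and at 5 FPKM or more in another, which leaves 75 higher and 133 lower genes.

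The highest genes after NANOG itself, apart from those listed at 0, included AKR1B10 (log2 difference 2.71) and AKR1C1 (2.44), both aldo-keto reductases, and the interstitial collagenase MMP1 (2.53). SPP1, which encodes osteopontin, was higher by 2.49, the transmembrane glycoprotein gene GPNMB by 2.48, DNER by 2.25, the cytochrome P450 gene CYP1B1 by 2.20 and IGFBP5 by 2.03. IGFBP5 was the most abundant of these, at 39.6 FPKM in empty vector and 165 FPKM in NANOG cells. On the lower side stood the keratin gene KRT34 (-3.53, from 33.0 to 1.95 FPKM), CA9 (-3.14), PLAT, which encodes tissue plasminogen activator (-2.30), C12orf36 (-2.14), the transcription factor gene ARNT2 (-2.11) and NOG, which encodes the BMP antagonist noggin (-2.10). SMARCA4 was listed at 0 in empty vector cells against 19.7 FPKM with NANOG. RPL21, HNRNPC, PAK4, OBFC2A and RPL21P28 were listed at 0 in the NANOG GFP siRNA library against 781, 139, 26.5, 18.2 and 18.8 FPKM in empty vector cells, and stood at 663, 134, 25.7, 20.01 and 84.4 FPKM in the NANOG HDAC1 siRNA library. SNAR-E was listed at 0 in both NANOG libraries and at 7.45 FPKM in empty vector cells. RPL21 and RPL21P28 are near-identical in sequence, so their values are uncertain.

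All 19 measured genes of hypoxia and glycolysis were lower with NANOG, 6 of them by at least 2-fold, with a median log2 difference of -0.88 at percentile 0 among 10000 random lists matched on expression. Besides CA9, the stress-responsive NDRG1 differed by -1.70 (351 to 107 FPKM), the glycolysis regulator PFKFB4 by -1.59 and the mitophagy receptor BNIP3 by -1.52 (480 to 166 FPKM). In the list of unfolded protein and amino acid stress, 17 of 22 genes were lower (median -0.51, percentile 0), with DDIT3 (0.38) and HERPUD1 (0.20), named after their values were seen, among the higher. The unfolded protein genes HSPA5 (-0.13), SDF2L1 (-0.08) and XBP1 (-0.25), also named after their values were seen, differed little. VLDLR differed by -1.53, the mTORC1 inhibitor DDIT4 by -1.43, STC2 by -1.30 and the mitochondrial PEPCK gene PCK2 by -1.11. Of the cholesterol synthesis genes, 16 of 17 were lower (median -0.34, percentile 0), among them INSIG1 (-1.16), SREBF2 (-0.92) and DHCR7 (-0.72).

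Epithelial genes were also lower as groups. The basal epithelium list had 12 of 16 genes lower (median -0.38, percentile 0), with KRT15 at -1.49 and COL17A1 at -0.86, whereas KRT5 (0.79; at 555 FPKM in empty vector cells, 959 FPKM with NANOG and 540 FPKM with HDAC1 siRNA) and KRT6A (0.73) were higher. In the columnar epithelium list 13 of 17 genes were lower (median -0.33, percentile 0.01), with the mucin gene MUC1 at -1.29, OCLN at -0.66 and CLDN7 at -0.60, and with KRT8 higher by 0.58. Stem cell markers and drug transporters had 8 of 10 genes lower (median -0.46, percentile 0.02); ALDH1A3 was higher by 1.09, ABCC1 lower at -0.75, ABCC2 at -0.61 and CD24 at -0.54. This list no longer stood apart by its mean (-0.24, percentile 3.36) or with no filter on low values (median -0.06, percentile 4.195). All 4 study genes were lower (median -0.38, percentile 1.82), but the list was taken from the study of these cells and is not independent evidence of its direction; by the mean it lay at percentile 4.75.

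Interferon-stimulated genes were higher in 17 of 24 cases (median 0.46, percentile 100). The ubiquitin-like ISG15 was at 489 FPKM in empty vector and 922 FPKM in NANOG cells (0.92), and the chemokine CXCL10 differed by 0.86, OASL by 0.75 and IFIT3 by 0.73. Replication-dependent histone genes were higher in 7 of 8 cases (median 0.33, percentile 99.4), with HIST1H3D at 0.84, HIST1H4E at 0.65 and HIST1H2AG at 0.63. That median was 0.25 at percentile 96.0 once a trend with transcript length (Spearman's rho -0.22 across genes) had been removed.

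The other 16 lists lay within the range of random lists. The closest were the p53 target genes (median 0.14, percentile 97.2), which stood apart under 5 alternatives (highest percentile 98.5), and the MHC class I presentation genes (0.17, percentile 96.5). Of the 18 MHC class I genes only 12 were measured. HLA-E, TAP1, TAPBP, PSMB8 and PSMB9, named after their values were seen, were listed at 0 in all 3 libraries. The G1/S list had a median of 0.06 (percentile 82.6) but a mean of 0.15 at percentile 98.1, and the G2/M list a median of 0.06 (percentile 83.3). CCND1, which encodes cyclin D1, was higher by 1.18 and RRM2 by 0.76. CDK inhibitors and pocket proteins had a median of -0.04 (percentile 36.6), with CDKN1C at 0.62. The pro-apoptotic BCL2 family had a median of 0.02 (percentile 62.6), with BNIP3L at -1.65 and BOK at -0.91, and its mean was -0.24 at percentile 2.11. Pro-survival genes had a median of -0.20 (percentile 8.47), with BCL2L1 at -0.54. Medians were -0.12 for class I HDACs and corepressor complexes (percentile 9.07), -0.18 for the 3 measured pluripotency genes (18.6), -0.07 for squamous differentiation (30.8; 1.06 with no filter on low values) and 0.01 for mesenchymal genes (55.6), where FN1 at -1.59 and VIM at 0.92 went opposite ways. They were 0.01 for NF-kB and inflammatory genes (57.8), 0.05 for immediate early genes (72.7), 0.01 for neuronal REST targets (51.7; 98.5 with a filter at 5 FPKM), -0.02 for genes raised by HDAC inhibitors (42.4) and -0.03 for cytoplasmic ribosomal proteins (24.2). In all, 9 of 25 lists stood apart, where lists of unrelated genes would give 1.25. Genes of 1 list can vary together between any 2 cultures, so more can stand apart without an effect of NANOG. Lists that share genes are not independent either.

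**Figure D2:**
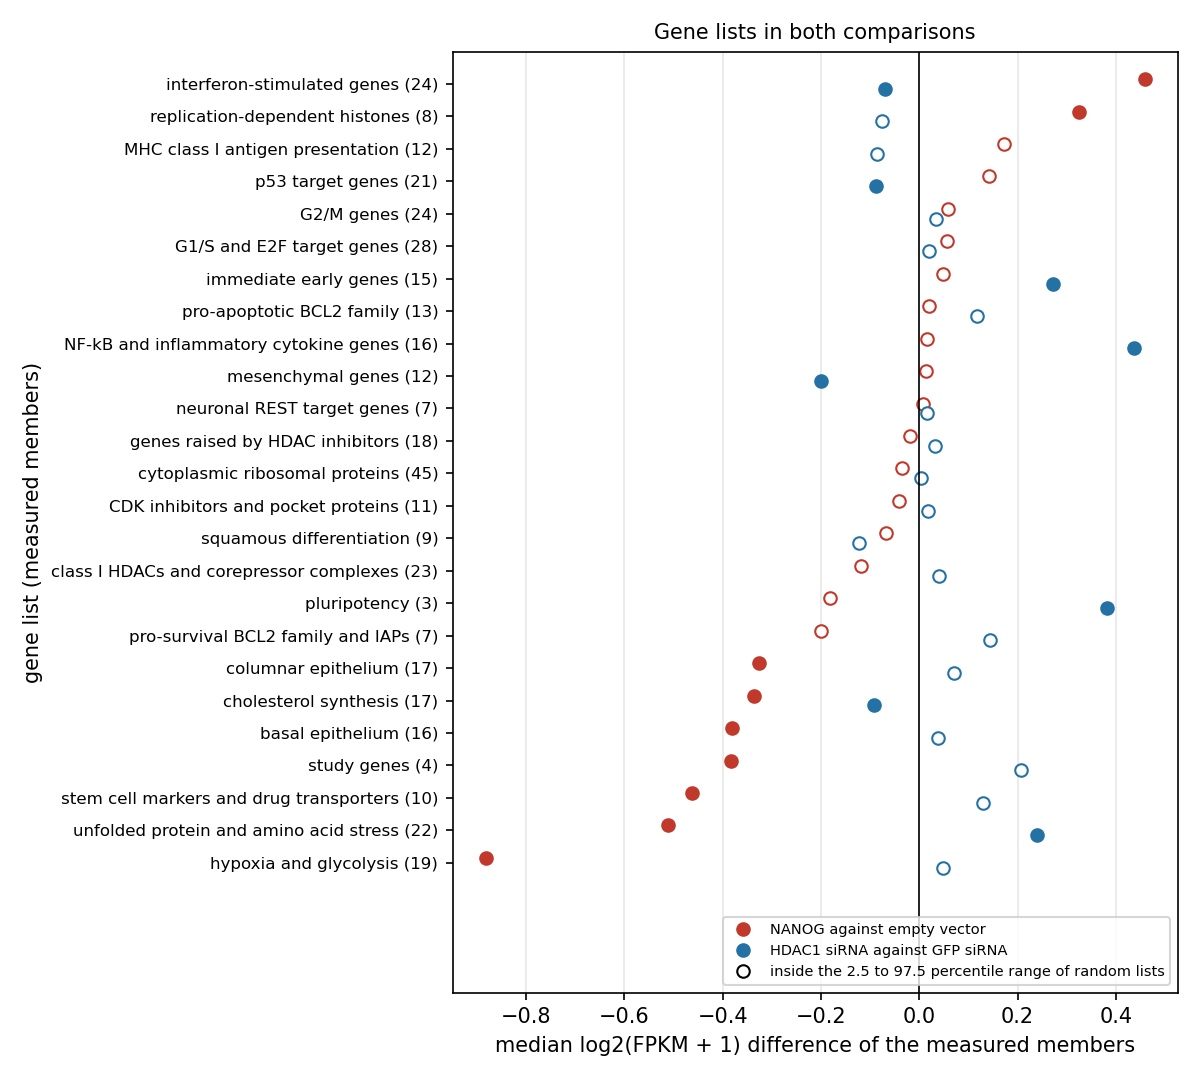
Median log2(FPKM + 1) difference of each gene list with at least 3 measured members, for NANOG against empty vector and for HDAC1 siRNA against GFP siRNA in NANOG cells; filled points lie outside the limits set from random lists. The hypoxia and glycolysis list is lowest with NANOG (-0.88) and the NF-kB and inflammatory list is highest with HDAC1 siRNA (0.44).

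The second comparison asked what differed in NANOG cells between HDAC1 siRNA and GFP siRNA. Inflammatory genes and immediate early genes were higher with HDAC1 siRNA, as were most genes of the joint list of unfolded protein and amino acid stress. CCL20, a chemokine gene, was at 1.24 FPKM with GFP siRNA and 6.15 FPKM with HDAC1 siRNA. Far fewer genes differed than with NANOG: 10 were at least 2-fold higher and 24 at least 2-fold lower. The 10 higher genes included the 5 listed at 0 in the NANOG GFP siRNA library and P2RX6P, listed at 0 in that library and at 5.74 FPKM with HDAC1 siRNA, so that 4 remained without them. Rescaling each library to TPM gave 21 higher and 17 lower genes, a scaling that moved the median of all genes from 0.01 to 0.18. The sums used for TPM included the small RNA symbols left out elsewhere. They were 681947 FPKM with GFP siRNA and 600749 FPKM with HDAC1 siRNA in NANOG cells, against 524374 and 504674 FPKM without small RNAs.

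After the genes listed at 0, the highest were CCL20 (1.68), HMGA2, which encodes an architectural chromatin protein (1.13), C17orf61-PLSCR3 (1.05), IL8 (0.98, from 43.3 to 86.3 FPKM), the decoy receptor gene IL1R2 (0.94) and SLC12A7 (0.85). The lowest after HDAC1 were NCL, which encodes nucleolin (-1.95), C11orf51 (-1.80), CTSD, which encodes cathepsin D (-1.66), NCS1 (-1.54), AKR1B10 (-1.53), ASPH (-1.46), PPM1G (-1.44), HMOX1, which encodes heme oxygenase (-1.41), WDR18 (-1.38), CCND1 (-1.35) and TCTA (-1.26). Most of these were high in the NANOG GFP siRNA library alone. NCL was at 135 FPKM in empty vector cells, 474 FPKM with NANOG and 122 FPKM with HDAC1 siRNA, and CTSD at 111, 327 and 103 FPKM. NCL, C11orf51 and PPM1G have a coding window of 30 codons in which a share of 1, 0.8 and 0.733 of codons start with GA, as codons for aspartate and glutamate do. The 46 genes with a share of 0.8 or more, among them NCL and C11orf51, lay above the mean of the other libraries in the NANOG GFP siRNA library by a median of 0.11 and below it in the HDAC1 siRNA library by a median of -0.13. Without the genes high in the NANOG GFP siRNA library alone, the remaining 38 had medians of 0.04 and -0.07.

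NF-kB and inflammatory cytokine genes were higher in 14 of 16 cases (median 0.44, percentile 100). CSF2, which encodes the growth factor GM-CSF, differed by 0.82 and the NF-kB inhibitor TNFAIP3 by 0.70, beside CCL20 and IL8. Immediate early genes were higher in 13 of 15 cases (median 0.27, percentile 100), with ZFP36 at 0.45, MYC at 0.41, KLF6 at 0.41 and FOSL1 at 0.40. Genes of unfolded protein and amino acid stress were higher in 19 of 22 cases (median 0.24, percentile 100), with SESN2 at 0.71, VLDLR at 0.71, STC2 at 0.59 and TRIB3 at 0.53. The unfolded protein genes HERPUD1 (-0.38), DDIT3 (-0.21) and DNAJB9 (-0.11), named after their values were seen, were lower. VLDLR remained below its empty vector level of 33.9 FPKM, at 11.1 FPKM with NANOG and 18.8 FPKM with HDAC1 siRNA. The 3 measured pluripotency genes were higher (median 0.38, percentile 99.7), with SALL4 at 0.47, KLF4 at 0.38 and DNMT3B at 0.19, and without the filter on low values the list was at percentile 50.3.

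Mesenchymal genes were lower in 10 of 12 cases (median -0.20, percentile 0.04), with TGFBI at -0.59 and COL1A1 at -0.38. Cholesterol synthesis genes were lower in 14 of 17 cases (median -0.09, percentile 0.86; 0.09 under TPM, at percentile 1.14), with CYP51A1 at -0.45. Interferon-stimulated genes were lower in 18 of 24 cases (median -0.07, percentile 1.66; 0.10 under TPM, at percentile 1.03, and percentile 5.02 with no filter on low values), with IFITM1 at -0.64 and OAS1 at -0.63. The p53 target genes had a median of -0.09 (percentile 1; 0.09 under TPM, at percentile 1.77) but a mean of 0.01 (percentile 50.5), with 10 genes higher and 11 lower, SESN2 at 0.71 and FAS at -0.44. TPM moved the median of all genes to 0.18, so these lists stayed below it.

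The hypoxia and glycolysis list lay within the range of random lists (median 0.05, percentile 78.8), as did genes that HDAC inhibitors are known to raise (0.03, percentile 64.9), where KLF6 differed by 0.41 and CLU by -0.46. The 4 study genes were all higher (median 0.21, percentile 97.4), just inside the range of random lists and again not independent evidence; they stood apart under 5 alternatives (highest percentile 98.7). The pro-apoptotic BCL2 family (0.12, percentile 96.4), pro-survival genes (0.14, percentile 95.9), stem cell markers and drug transporters (0.13, percentile 96.7), MHC class I presentation (-0.09, percentile 3.23) and squamous differentiation (-0.12, percentile 3.37) were likewise inside. Of these, the pro-apoptotic family reached percentile 99.96 with a filter at 5 FPKM, pro-survival genes 98.3 with no filter and MHC class I presentation 1.44 by its mean, each standing apart under 2 alternatives. CALR of the MHC class I list differed by -0.93, but it was high in the NANOG GFP siRNA library alone. It was at 316 FPKM in empty vector cells, 537 FPKM with NANOG and 282 FPKM with HDAC1 siRNA. NT5E of the stem cell list differed by 0.42. Medians were 0.04 for basal epithelium (percentile 72.4), 0.07 for columnar epithelium (87.3), 0.02 for CDK inhibitors and pocket proteins (53.4), 0.04 for class I HDACs and corepressor complexes (65.0), 0.02 for G1/S genes (45.4), 0.03 for G2/M genes (60.0), 0.02 for neuronal REST targets (57.8), -0.08 for histones (21.1) and 0.00 for ribosomal proteins (33.1). In this comparison 8 of 25 lists stood apart. Cancer-testis antigens had 0 measured members and mitochondrially encoded genes 0. Among 20 leukocyte and endothelial markers only CD68 was measured, at 50.7, 61.2 and 53.5 FPKM in the 3 libraries.

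**Figure D3:**
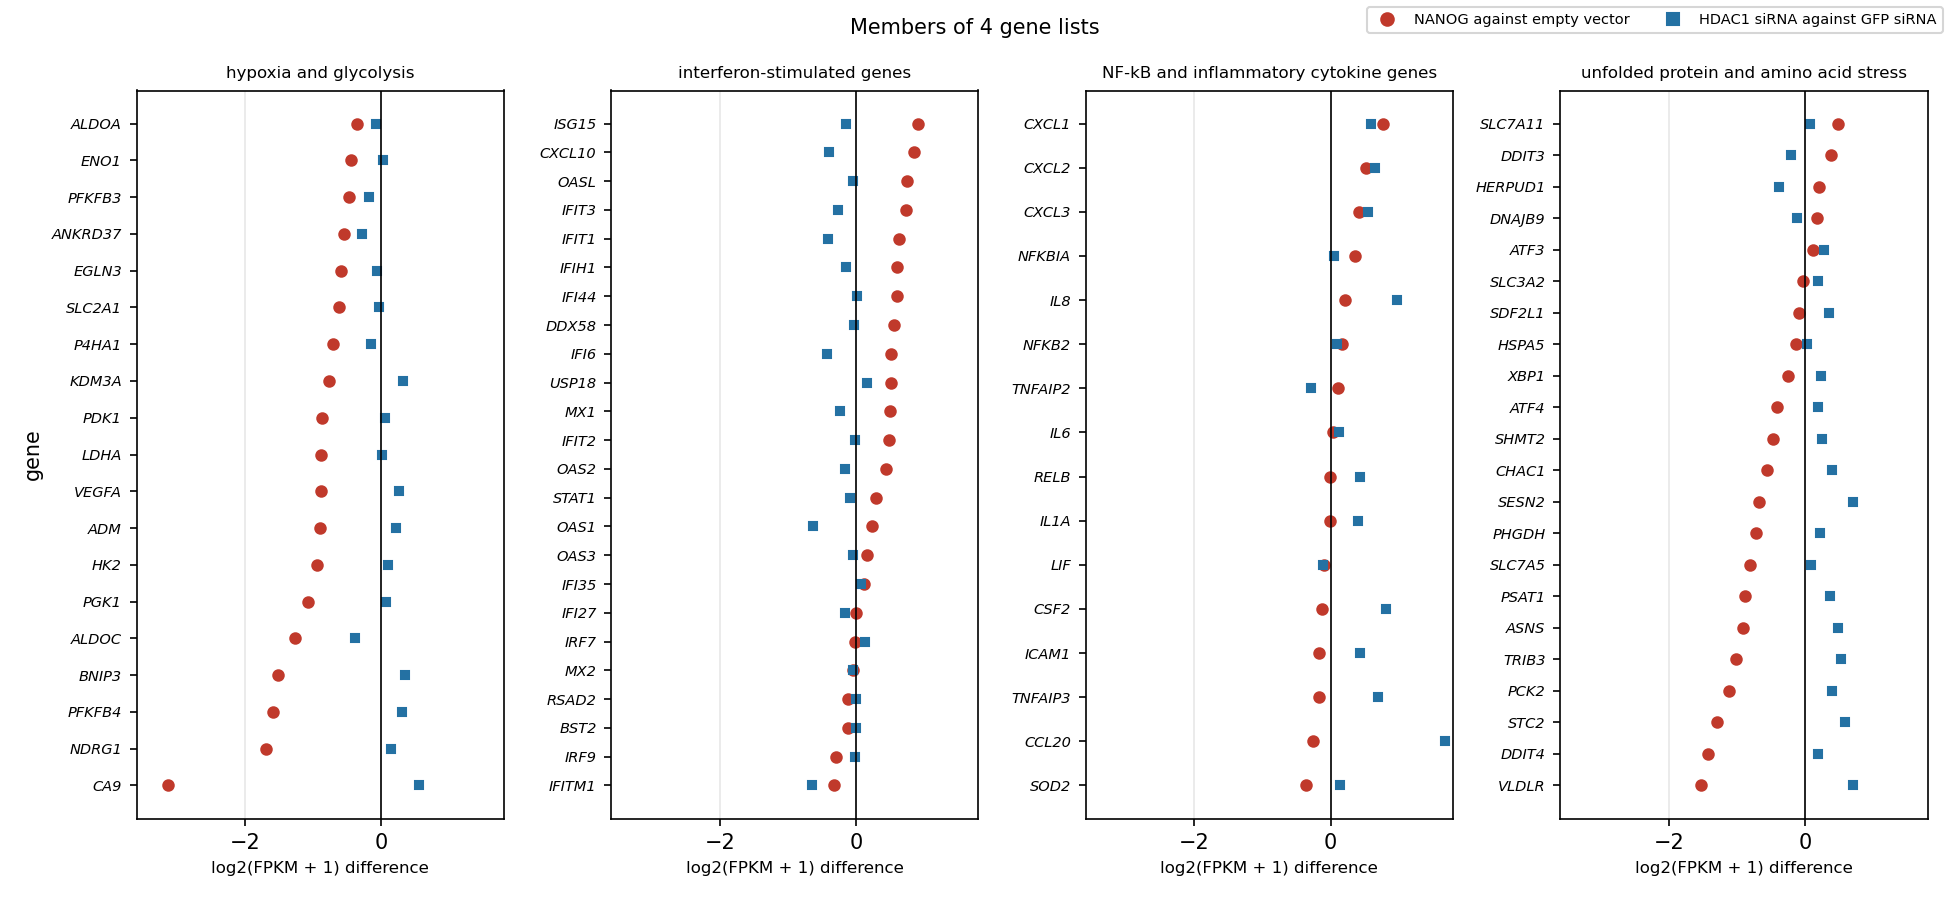
Log2(FPKM + 1) difference of every measured member of 4 gene lists, circles for NANOG against empty vector and squares for HDAC1 siRNA against GFP siRNA. The 19 hypoxia and glycolysis genes all lie below 0 with NANOG, and 14 of 16 inflammatory genes lie above 0 with HDAC1 siRNA.

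The third comparison asked which genes moved one way with NANOG and the other way with HDAC1 siRNA. HDAC1, NCL, C11orf51, CTSD, AKR1B10, ASPH, HMOX1, NCS1, WDR18 and PPM1G led the genes that were higher with NANOG and lower with HDAC1 siRNA. In all, 18 genes differed so by at least 2-fold both times, 17 of them without the genes listed at 0, NANOG and HDAC1. In the other direction 5 genes did, and these were RPL21, HNRNPC, PAK4, RPL21P28 and OBFC2A, all listed at 0 in the shared library. The next were IL1R2 (-1.21, then 0.94), INHBA, which encodes an activin subunit (-0.98, then 0.85), SLC16A13 (-1.49, then 0.83) and KRT34 (-3.53, then 0.83). IL1R2 went from 11.9 FPKM in empty vector cells to 4.58 FPKM with NANOG and 9.73 FPKM with HDAC1 siRNA.

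Genes picked for a large difference with NANOG tend to move back with HDAC1 siRNA by selection alone, since both comparisons use the NANOG GFP siRNA library. Of the 73 genes at least 2-fold higher (without genes listed at 0, NANOG and HDAC1), 65 were lower with HDAC1 siRNA, by a median of -0.48 against a median of 1.23 with NANOG, and 24 stayed at least 2-fold above empty vector cells. These 65 are 89.0%, where values reassigned at random among the libraries of each gene gave a mean of 93.1% (central 95% 86.4% to 98.4%). By at least 2-fold 17 moved back, or 23.3% against 55.9% (44.4% to 66.7%). Of the 133 genes at least 2-fold lower with NANOG, 107 were higher with HDAC1 siRNA, by a median of 0.19 against -1.30, and 82 stayed at least 2-fold below empty vector cells. These 107 are 80.5% against 71.8% under reassignment (59.6% to 82.5%), and 0 moved back by at least 2-fold against 13.9% (7.14% to 21.8%). AKR1B10 stayed above empty vector cells by 1.18 and KRT34 below at -2.70. CA9 stayed below at -2.58. NANOG cells with HDAC1 siRNA differed from empty vector cells by at least 2-fold in 42 genes that were higher and 94 that were lower. That comparison leaves out the shared library, and 12 of 25 lists stood apart in it. Hypoxia and glycolysis genes (median -0.83, percentile 0), cholesterol synthesis genes (-0.45, percentile 0) and genes of unfolded protein and amino acid stress (-0.20, percentile 0.08) were lower, and NF-kB and inflammatory genes (0.43, percentile 100) and immediate early genes (0.22, percentile 99.95) were higher. Histone genes (0.28, percentile 99.8), interferon-stimulated genes (0.22, percentile 100) and G1/S genes (0.13, percentile 99.5) were higher too. Of the G1/S genes 16 were higher and 12 lower. Basal epithelium genes (-0.28, percentile 0) and columnar epithelium genes (-0.23, percentile 0.095) were lower. Mesenchymal genes (-0.20, percentile 1.04) and stem cell markers and drug transporters (-0.19, percentile 1.76) were lower too, but no longer stood apart under 3 alternatives each.

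The NANOG GFP siRNA library enters both comparisons with opposite signs, so opposite changes arise by chance. Across the 11390 genes without those listed at 0, NANOG and HDAC1, Pearson's r between the changes was -0.57, where values reassigned at random among the libraries of each gene gave -0.50 (range of the central 95% -0.52 to -0.47). The covariance was -0.0457 against a reassigned mean of -0.0455, and 70.4% of genes had opposite signs against 66.6% (65.8% to 67.5%). The slope of the second change on the first was -0.34 against the reassigned -0.50 (-0.53 to -0.47). The 17 genes higher then lower compare with a mean of 33.7 under reassignment (24 to 43) and 0.147 for independent lists, and the 0 genes lower then higher with 8.27 (4 to 13) and 0.0467. Reassignment treats the 3 libraries as alike, whereas the SD of log2 differences across genes was 0.406 and 0.324 for empty vector against the NANOG libraries and 0.262 between these. A NANOG effect kept in both NANOG libraries by itself lowers the size of the slope and of r, these counts, and the shares of opposite signs and of genes moving back. Values smaller in size than the reassigned ones thus say nothing about HDAC1 siRNA. Such an effect does not account for r, the share of opposite signs or the 80.5% of lower genes moving back, which lay inside its reassigned range. Larger chance deviations in the shared library than in the others would raise these too. With 1 library per group the shared library could not be split.

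**Figure D4:**
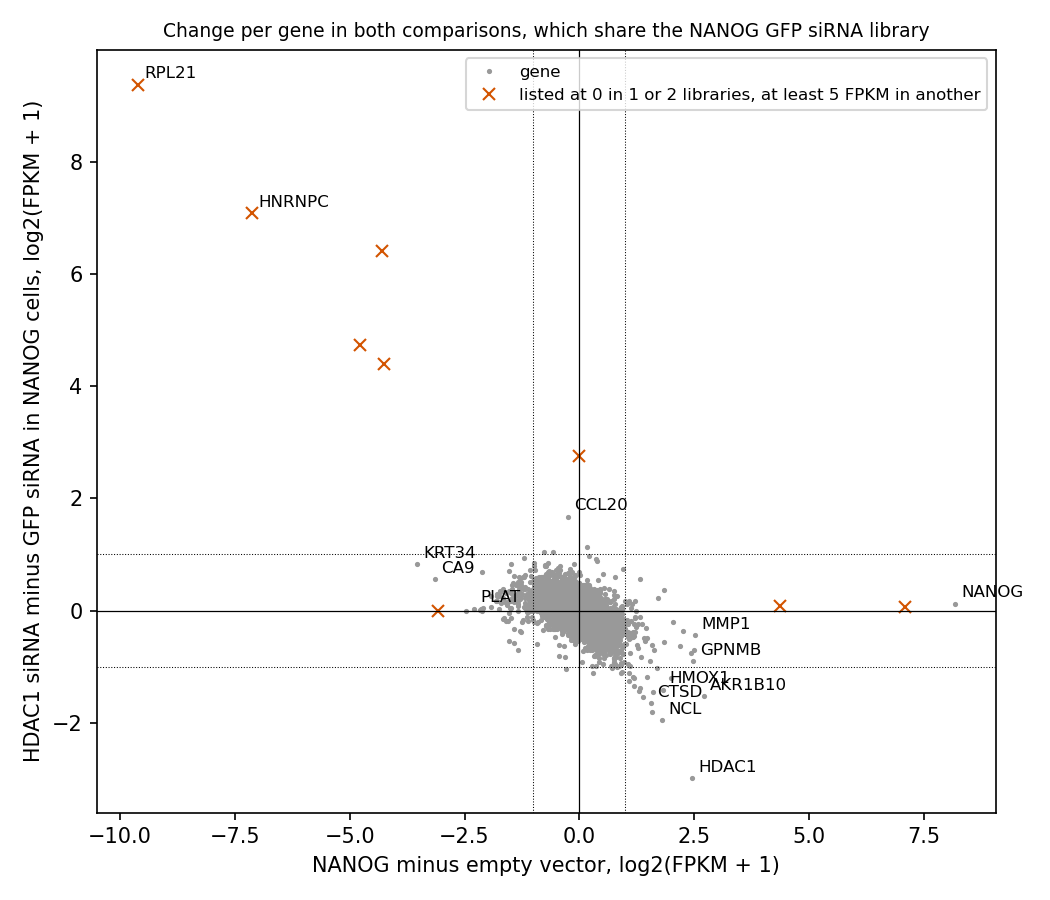
Log2(FPKM + 1) difference of each of 11401 genes for NANOG against empty vector (horizontal axis) and HDAC1 siRNA against GFP siRNA (vertical axis); crosses are genes listed at 0 in a library, dotted lines mark 2-fold. The 5 crosses at upper left are all genes of the lower then higher class, and HDAC1 lies at 2.45 and -2.98.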

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

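The limit of 1000 FPKM used for this search was chosen after seeing the data. Small RNA symbols, which the comparisons leave out, held 4 values above that limit in a NANOG library where the empty vector library was listed at 0. The reverse, such values in the empty vector library with 0 in a NANOG library, was not searched. A link with NANOG can therefore not be read from them. MIR762 was at 24077 FPKM in the NANOG GFP siRNA library and listed at 0 in both other libraries. SNORD55 was at 65956 FPKM in the NANOG GFP siRNA library and listed at 0 in both others. SNORD5 was at 66160 FPKM and SNORD76 at 28269 FPKM in the NANOG HDAC1 siRNA library, and both were listed at 0 in the other libraries. No explanation was tested for these values.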

How the results depend on the processing

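The alternatives without genes listed at 0, without genes of acidic stretches and with the length trend removed were added after seeing the data; the others were planned. No paired analysis was possible because each group had 1 library, and no library could be left out. With a pseudocount of 0.1 FPKM, 138 genes were higher and 216 lower with NANOG, 21 higher and 47 lower with HDAC1 siRNA, 12 were lower then higher, and the NANOG difference was 11.1; it was 9.12 at 0.5 FPKM. Smaller pseudocounts give low values more weight by construction. Under TPM, 21 genes were higher with HDAC1 siRNA and 10 lower then higher, the NANOG difference was 8.70 (0.31 under HDAC1 siRNA), the HDAC1 difference under HDAC1 siRNA was -2.84, and the medians of p53 targets (0.091), interferon-stimulated genes (0.10) and cholesterol synthesis (0.0896) became positive with the shift of the median of all genes to 0.18, while their percentiles stayed low at 1.77, 1.03 and 1.14. The mean of the p53 targets, 0.0065, was also positive under HDAC1 siRNA. With small RNAs kept, 26 genes were higher and 49 lower with HDAC1 siRNA, 9 were lower then higher, 33 higher then lower, and r was -0.51; the cause was not tested. A threshold of 1.5-fold gave 396 higher and 600 lower genes with NANOG, 77 and 163 with HDAC1 siRNA, 39 lower then higher and 95 higher then lower. At 3-fold these were 21 and 34 with NANOG, 4 lower with HDAC1 siRNA and 2 higher then lower. Without genes listed at 0, 4 genes were higher with HDAC1 siRNA and 0 lower then higher. The other 115 values of the main results stayed within 1.5 times for counts and 0.1 for log2 values. For r the limit was the central 95% of values from resampling genes. This r was taken over all 11401 genes, where it was -0.61 in the main run. Of the values of named genes, 2704 stayed within 0.1 and 250 moved by more. For NANOG cells with HDAC1 siRNA against empty vector cells, 21 counts stayed within 1.5 times and 7 moved by more. Of the list values, 925 kept their direction and their side of the limits, 24 newly stood apart, 13 no longer did and 4 reversed; 3 of these 4 are the TPM medians above, which kept their side of the limits. Keeping the largest entry of a repeated symbol moved nothing, since no symbol was repeated. Unknown depth leaves the error of low genes open.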

Other observations

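All tests and gene lists in this part were chosen after the results were seen. Genes of the antioxidant response, known targets of the transcription factor NRF2, were higher with NANOG in 18 of 19 measured cases, with a median log2 difference of 0.86 (percentile 100 among random lists), and lower with HDAC1 siRNA in 17 of 19 (median -0.36, percentile 0), 2 comparisons that share the NANOG GFP siRNA library. NQO1, a quinone reductase, was at 205 FPKM in empty vector cells, 639 FPKM with NANOG and 394 FPKM with HDAC1 siRNA. AKR1C3 was at 34.8, 127 and 85.6 FPKM, and the ferritin light chain gene FTL at 8470, 20074 and 13086 FPKM. ABCC2 was the exception in both comparisons, at 2.86, 1.53 and 2.63 FPKM, and SLC7A11 the other one with HDAC1 siRNA, at 27.1, 38.4 and 40.3 FPKM. The list was assembled because AKR1B10, AKR1C1 and HMOX1 had large differences. Without these 3 genes 14 of 16 were lower with HDAC1 siRNA (median -0.26), and in NANOG cells with HDAC1 siRNA against empty vector cells the median was 0.37 at percentile 100. With NANOG it was 0.66 at percentile 100, which is consistent with a group difference in NRF2 targets; 1 library per group cannot separate this from a difference between the cultures.

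The matrix metalloproteinase list was taken up because of MMP1. Without it, 3 of 4 measured genes were higher with NANOG (median 0.52, percentile 99.8), but NANOG cells with HDAC1 siRNA differed from empty vector cells by 0.14 (percentile 86.8). MMP13 was at 0.312, 2.31 and 0.878 FPKM and MMP3 at 4.23, 9.10 and 15.9 FPKM, while MMP14 was at 16.1, 11.6 and 12.3 FPKM. High CTSD and GPNMB with NANOG raised the question of lysosomal genes as a group. Without CTSD, 16 lysosomal genes had a median of 0.12 at percentile 92.76 with NANOG, inside the range of random lists, which neither shows nor excludes a shift of the group. With HDAC1 siRNA the same 16 had a median of -0.14 at percentile 0.07, and 12 of them were lower, but against empty vector cells these HDAC1 siRNA cells had 0.02 at percentile 56.6, so the shift was seen only against the NANOG GFP siRNA library.

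Genes listed at 0 were the first pattern. Among genes at 10 FPKM or more in both other libraries, 7 were at exactly 0 in the remaining one (2 in empty vector cells, 5 with NANOG and GFP siRNA, 0 with HDAC1 siRNA), and apart from NANOG no gene lay between 0 and 1 FPKM. A true loss of transcripts would tend to leave intermediate values too. Failed estimates in the authors' quantification are thus a candidate explanation for all 7. The ribosomal protein gene RPS18 and the MHC class I genes HLA-E, TAP1, TAPBP, PSMB8 and PSMB9 were listed at 0 in all 3 libraries. These genes were named after their values were seen. That is a different pattern and says nothing about zeros in 1 library. Loss with NANOG whatever the HDAC1 level is argued against: 2 of the 7 were at 0 in empty vector cells, and the 5 genes at 0 with NANOG were all at 10 FPKM or more in the HDAC1 siRNA library, which carries NANOG too. A loss that needs both NANOG and HDAC1 would give this return for the 5. It would leave weaker cases too. There were 0 genes between 0 and 1 FPKM there, and 0 of 11390 other genes were at least 2-fold lower then higher. At 1.5-fold, however, 34 genes without those listed at 0 were lower then higher. The number expected by chance at that limit was not computed, so this explanation stays open.

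Genes high in the NANOG GFP siRNA library alone were the second pattern: 46 genes were at least 0.7 above both others, which lay within 0.35 of each other, against 4 such genes in the HDAC1 siRNA library and 179 in the empty vector library, where both other libraries carry NANOG. A bias of that library at acidic coding stretches, a property picked after many sequence features had been looked at, stays open for the genes that have one: the 46 genes with a share of 0.8 or more had medians of 0.113 there and -0.127 in the HDAC1 siRNA library, but 0.0364 and -0.0750 for the 38 left without genes of the pattern, which takes out the highest; of these 38, 13.2% still deviated there by 0.5 or more, against 2.49% of all genes without the pattern. As the whole cause it is argued against: of 43 genes of the pattern with a sequence, 23.3% had a share of 0.6 or more, which is above the 2.43% of all genes but leaves most without one, and genes with a share of 0.4 to 0.6 had a median of -0.0104. A trend common to genes of like transcript length is argued against, as 40 of the 43 genes kept the difference after that trend was removed. For HDAC1, whose share is 0.467, the 759 genes of like share deviated in that library from the mean of the others by a median of -0.0134. Of these genes 21 deviated by 0.5 or more. Those above 0 in all libraries, NANOG aside, deviated by at most 1.53, against 2.72 for HDAC1. This argues against a bias common to such genes as its whole cause, but not against an error of that library at single genes. A NANOG effect on HDAC1 stays open too, as an untested hypothesis.

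The opposite changes were the third pattern. Chance deviations of the shared library and a reversal of NANOG effects by HDAC1 siRNA cannot be told apart here. The correlation of -0.57 and the 70.4% of genes with opposite signs (against 65.8% to 67.5%) lay beyond the reassigned range, and the covariance inside it. A lasting NANOG effect by itself would lower the size of both, so it does not account for them. Reassignment treats the libraries as alike, however, and larger chance deviations in the shared library than in the others would raise both. No second NANOG GFP siRNA library was analysed. Less NANOG in the HDAC1 siRNA cells is argued against, since NANOG differed by 0.12 and was the higher there.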
